A study of Oryza sativa with 2 samples.

How the data were processed

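Total RNA came from whole seedlings and the libraries were made with a kit for Illumina sequencing, per the labels' protocols. The control group and the fluoride group had 1 library each. The table's column for treated seedlings was taken as the fluoride library, since it was the only treated sample. Per the submitters' processing notes, reads were counted with featureCounts and compared with DESeq2, and no versions are given. The aligner, the assembler's settings and the filters are not given in the sources used here. Transcript identifiers are those of a Trinity assembly, per the file headers.

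The deposited expression signal is a normalized count per transcript: every value above 0 was a whole multiple of 1 step per library (100% of values within 0.01 reads), so the whole reads could be recovered. 1 read was worth 1.10 normalized counts in the control and 0.907 in the fluoride library. The 100 most abundant transcripts held 25.3% of the control reads and 19.6% of the fluoride reads. The authors' deposited comparison table gives a log2 fold change with its error, a test statistic used here as a score only to describe the file, and an unadjusted and an adjusted p-value, per the file headers. A further deposited table gives a p-value per gene ontology term. The deposited annotation gives best protein hits with their descriptions and species. The search program and its limits are not given in the sources used here.

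From these values the log2 ratio of fluoride over control was computed as log2(value + 1), which understates the change of low transcripts. Transcripts with a mean of at least 10 normalized counts were kept, and a fold of at least 2 was counted as higher or lower. With 1 library per group no test of the conditions was made across genes. Beside named transcripts stands the ratio of normalized counts with an exact conditional binomial (Clopper-Pearson) 95% interval from the recovered reads, which compares the libraries. Shares of reads and shares of list members have exact binomial intervals. The intervals on list members treat the members as independent draws, although transcripts of 1 gene may be among them. A transcript with 0 reads in 1 library is given as at least N-fold against a floor of 3 reads in that library. Reads were counted without molecular identifiers, so intervals on reads and floors cover counting error only, and transcripts of near-identical copies may share reads.

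The 41 gene lists were regular expressions fixed before the data were examined and matched to the joined UniRef and UniProt descriptions, so that a list can hold other products with a matching description. For each list the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. 6 more lists were written after the data were examined. Each transcript was placed in a taxon group by the first word of its best hit's species, using a table written after the species names were seen. Transcripts with no species but a rice locus name counted as plant.

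Named transcripts followed a rule fixed before the data were examined: the 12 highest and 12 lowest ratios among transcripts with a mean of at least 50 and an informative description, the 2 most abundant members and up to 2 with the largest absolute ratio of each list, every enolase, chloride channel or fluoride exporter, the 4 most abundant reference genes and the first 5 terms of the authors' ontology table. The same rule was applied to plant hits alone after the data were examined. Descriptions such as expressed protein were treated as uninformative.

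The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures. They were tested on counts simulated for the fluoride against control comparison, with 200 transcripts changed by known folds. These 200 all had a mean of at least 50, so recovery of changes at a mean of 10 to 50 was not tested. The simulated counts held Poisson counting error alone, with no variation between plants or libraries. The rates of calls below are therefore not false-call rates for the real libraries. Of the 50 changed 2.5-fold, 96.0% were called at least 2-fold in the right direction, of the 50 changed 4-fold 100%, and of the 50 changed 1.5-fold 0%. Of 24207 unchanged transcripts with a mean of at least 10, 1.85% were called at least 2-fold. The 95% ratio interval held the true ratio for 94.8% of 2000 transcripts, also with a mean of at least 50. The list check used the real ratios and not simulated counts, and 5.0% of 200 random lists fell outside the central 95%. A share near this value follows from drawing both from the same transcripts. It does not test lists of related genes or of several transcripts of 1 gene. Alternatives were pseudocounts of 0.5 and 5, other filters, 2 other scalings, sums over the same best hit, a fold of at least 4, plant hits alone and an exact test on the recovered reads. edgeR would need an assumed dispersion here and was not run.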

Results

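Whole rice seedlings (shoots and roots, indica cultivar IR-64, 25 days old) were grown in potting medium and watered either with distilled water (control) or with a sodium fluoride solution of 25 mg per litre (fluoride). 1 RNA-seq library was made per group, so no difference has a replicate check, and every statement compares 2 libraries and not 2 conditions. The table held 68009 transcripts assembled without a genome. The reads recovered from its normalized counts came to 12678835 in the control library, spread over 31434 transcripts, and to 12734030 in the fluoride library, spread over 42385 transcripts. Transcripts are named here by the description of their best protein hit. No chromosome positions go with them, because they are assembled sequences with no genome build. Intervals are 95%. Those on reads and ratios cover counting error only, and those on shares of list members treat the members as independent draws.

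The comparison asks which transcripts differ between fluoride-watered and control seedlings. Transcripts whose best hit was a fungal protein were, with few exceptions, higher in the fluoride library. Fungal hits took 3.61% of the fluoride reads (exact binomial interval 3.60 to 3.62%) and 0.0711% of the control reads (0.0696 to 0.0726%), a ratio of 50.8 (49.8 to 51.9). Among rice transcripts, xylanase inhibitor protein 2, momilactone A synthase and chitinase 1 were higher in the fluoride library, while the list of pathogenesis-related proteins and chitinases as a whole went both ways. Abundant photosynthesis transcripts such as the photosystem II 10 kDa polypeptide and plastocyanin were lower.

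Of 24159 transcripts with a mean of at least 10 normalized counts, 6521 were at least 2-fold higher and 2354 at least 2-fold lower in the fluoride library. Fungal hits supplied 3743 of the higher and 64 of the lower transcripts. Plant hits, a restriction chosen after the data were examined, numbered 18815, with 2352 higher and 2100 lower, so 52.8% of the called plant-hit transcripts were higher. That split was 71.4% when both libraries were scaled to the same total, which moves every log2 ratio up by 0.28. List medians below are therefore given relative to the median of plant-hit transcripts (-0.05 as deposited).

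**Figure D1:**
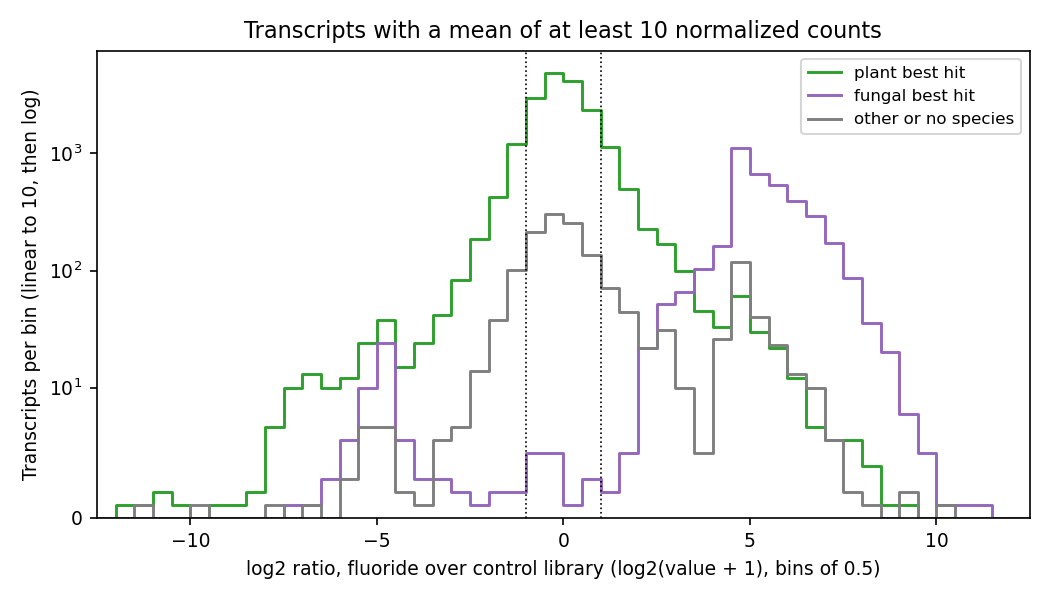
Number of transcripts per bin of log2 ratio (x axis, fluoride over control library, log2(value + 1), bins of 0.5) on a y axis that is linear to 10 and logarithmic above, for plant hits, fungal hits and all remaining transcripts with a mean of at least 10 normalized counts; dotted lines mark a 2-fold difference. Plant hits centre near 0 (median -0.05), while fungal hits have a median of 5.22.

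The fungal hits were led by relatives of Bipolaris (family Pleosporaceae, which holds leaf spot pathogens of grasses), with 4517 reads in the control and 368451 in the fluoride library. Of 2864 transcripts of this group with a mean of at least 10, 2841 were at least 2-fold higher and 21 at least 2-fold lower. Hits to Candida and related yeasts had 92 and 32669 reads, a ratio of shares of 354 (288 to 439). Smut fungi had 40 and 31624 reads, a ratio of 787 (578 to 1102), and Fusarium and relatives had 124 and 12533 reads, a ratio of 101 (84.3 to 121). Bacterial hits took 0.0179% of the control and 0.122% of the fluoride reads. They were not uniform, with 138 and 1830 reads for Cutibacterium but 248 and 21 for Azospirillum. Drosophila hits were close in both, with 0.118% and 0.113%. Fungal groups with few transcripts were not uniform: hits to Pseudogymnoascus had 712 control and 664 fluoride reads. Hits to Pyrenochaeta (447 and 294 reads) and Rachicladosporium (362 and 65) were lower in the fluoride library. Of 87 transcripts of other Dothideomycetes with a mean of at least 10, 51 were at least 2-fold higher and 36 lower.

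**Figure D2:**
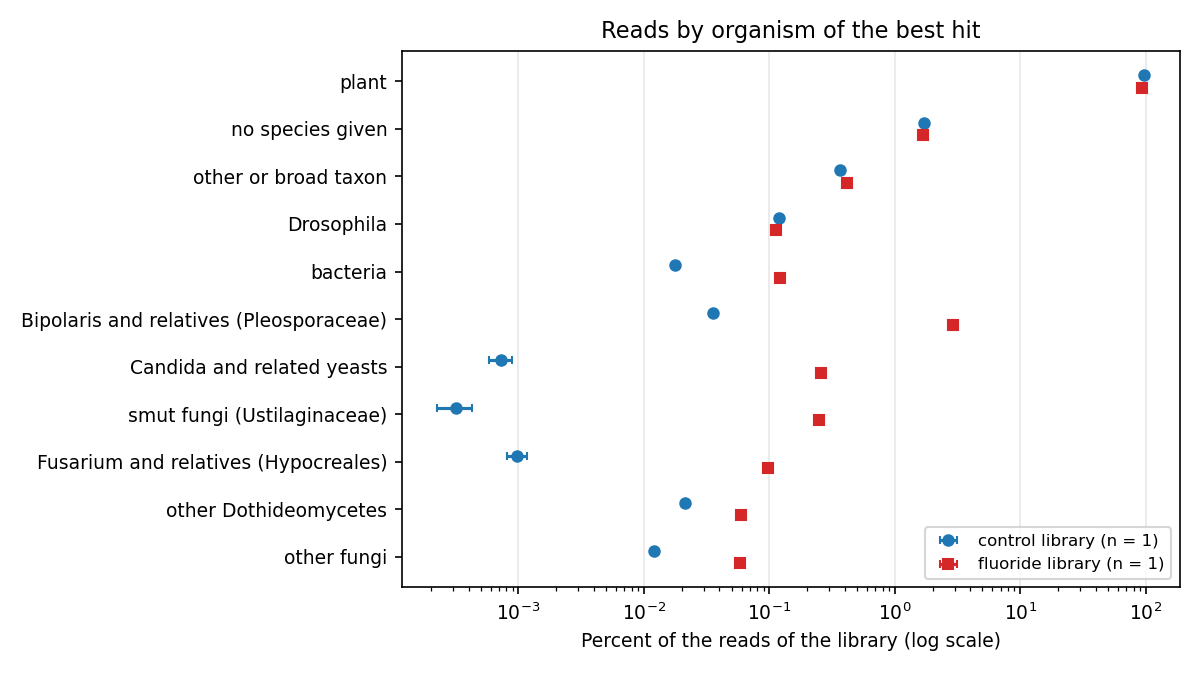
Percent of each library's reads (x axis, log scale) by organism of the best hit (y axis) for the control (circles) and the fluoride library (squares), 1 library each; bars are exact binomial 95% intervals and are mostly smaller than the symbols. Relatives of Bipolaris take 0.0356% of control and 2.89% of fluoride reads, Drosophila hits 0.118% and 0.113%.

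The named-transcript rule took the 12 highest and the 12 lowest ratios among well-described transcripts with a mean of at least 50. The highest was a Setosphaeria hit described as dibenzothiophene desulfurization enzyme C, with 0 control and 2629 fluoride reads, at least 720-fold higher against a floor of 3 reads. Others were a 1,3-beta-glucanosyltransferase that remodels the fungal cell wall (at least 443-fold), a probable polyol transporter (at least 338-fold) and a chitin deacetylase (at least 183-fold). The only plant hit among these 12 was xylanase inhibitor protein 2, which blocks microbial xylanases (TRINITY_DN128_c0_g3_i1). It had 9.93 normalized counts in the control and 6421 in the fluoride library, 647-fold higher (341 to 1415).

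The same rule restricted to plant hits named several genes of defence metabolism. Momilactone A synthase, which makes a rice diterpenoid phytoalexin (TRINITY_DN3393_c0_g2_i1), had 0 control and 254 fluoride reads, at least 69.6-fold higher. Ent-copalyl diphosphate synthase 2, an early enzyme of that class of compounds, had 0 and 154 reads, at least 42.2-fold higher. A vetispiradiene synthase-like transcript was at least 70.7-fold higher and WRKY transcription factor 27 at least 64.7-fold higher. Laccase-24 was 223-fold higher (113 to 518), glutathione S-transferase 4 was 202-fold higher (78.6 to 742), and tryptamine hydroxycinnamoyltransferase 1 was 198-fold higher (67.4 to 961). A cysteine-rich receptor-like kinase described as a DUF26 protein had 2 control and 1715 fluoride reads, a ratio of 705 (195 to 5824). A potassium transporter had 0 and 386 reads, at least 106-fold higher.

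The lowest transcripts were mostly rice proteins with no reads in the fluoride library. Os04g0478000 protein (TRINITY_DN177_c0_g4_i1) had 2922 control reads and 0 fluoride reads, at least 1185-fold lower. An aspartyl protease family protein similar to At5g10770 (TRINITY_DN136_c0_g3_i1) had 1878 and 0 reads, at least 762-fold lower. A cnd41-like aspartyl protease was at least 200-fold lower, FT-interacting protein 1, named for a regulator of flowering signal transport, at least 90.8-fold lower, and cysteine proteinase EP-B 1 at least 71.0-fold lower. 1 of these 12 was a fungal hit, a heat shock 70 kDa protein of Stagonospora with 132 control and 0 fluoride reads.

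Photosynthesis transcripts were lower in the fluoride library as a group. Of 23 plant-hit members of the photosystem and light harvesting list, 8 were at least 2-fold lower and 1 at least 2-fold higher. Only 3 members were higher at all (exact binomial interval 2.78 to 33.6% of members), and the list median lay 0.82 below the plant-hit median on the log2 scale, beneath all 10000 random lists matched on expression. Part of this goes with abundance, since the matched random lists had a typical median of -0.28, against -0.87 for the list. The photosystem II 10 kDa polypeptide was 2.98-fold lower (2.95 to 3.0), and plastocyanin, a copper protein that carries electrons to photosystem I, 2.03-fold lower (2.01 to 2.05). The photosystem II 22 kDa protein, which dissipates excess light, was 5.58-fold lower (5.16 to 6.03). Leaf markers, which share members with that list, behaved alike, with 0 of 17 at least 2-fold higher and 5 at least 2-fold lower. In chlorophyll biosynthesis, glutamyl-tRNA reductase was 2.32-fold lower (2.27 to 2.37) and the magnesium-chelatase 30 kDa subunit 2.06-fold lower (1.94 to 2.18), while the list of 15 members lay at percentile 31.5 of random lists. The Calvin cycle list was split, with 2 of 12 members at least 2-fold higher and 1 lower (percentile 74.0). However, 1 of the 2 higher members (2.22-fold, 1.81 to 2.74) is described as a methylthioribulose-1-phosphate dehydratase/enolase-phosphatase E1, which is not a Calvin cycle enzyme. The Rubisco small chain was 1.91-fold lower (1.87 to 1.95) and chloroplastic transketolase 1.49-fold lower (1.47 to 1.52). Root markers had 7 of 40 at least 2-fold higher and 6 lower, and their median lay 0.25 below the plant-hit median (percentile 3.0). Among them high-affinity nitrate transporter 2.4 was 16.1-fold lower (11.9 to 22.3), and 2 transcripts described as the silicon transporter LSI3 went apart, 2.28-fold lower (2.16 to 2.40) and 3.10-fold higher (2.61 to 3.69).

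**Figure D3:**
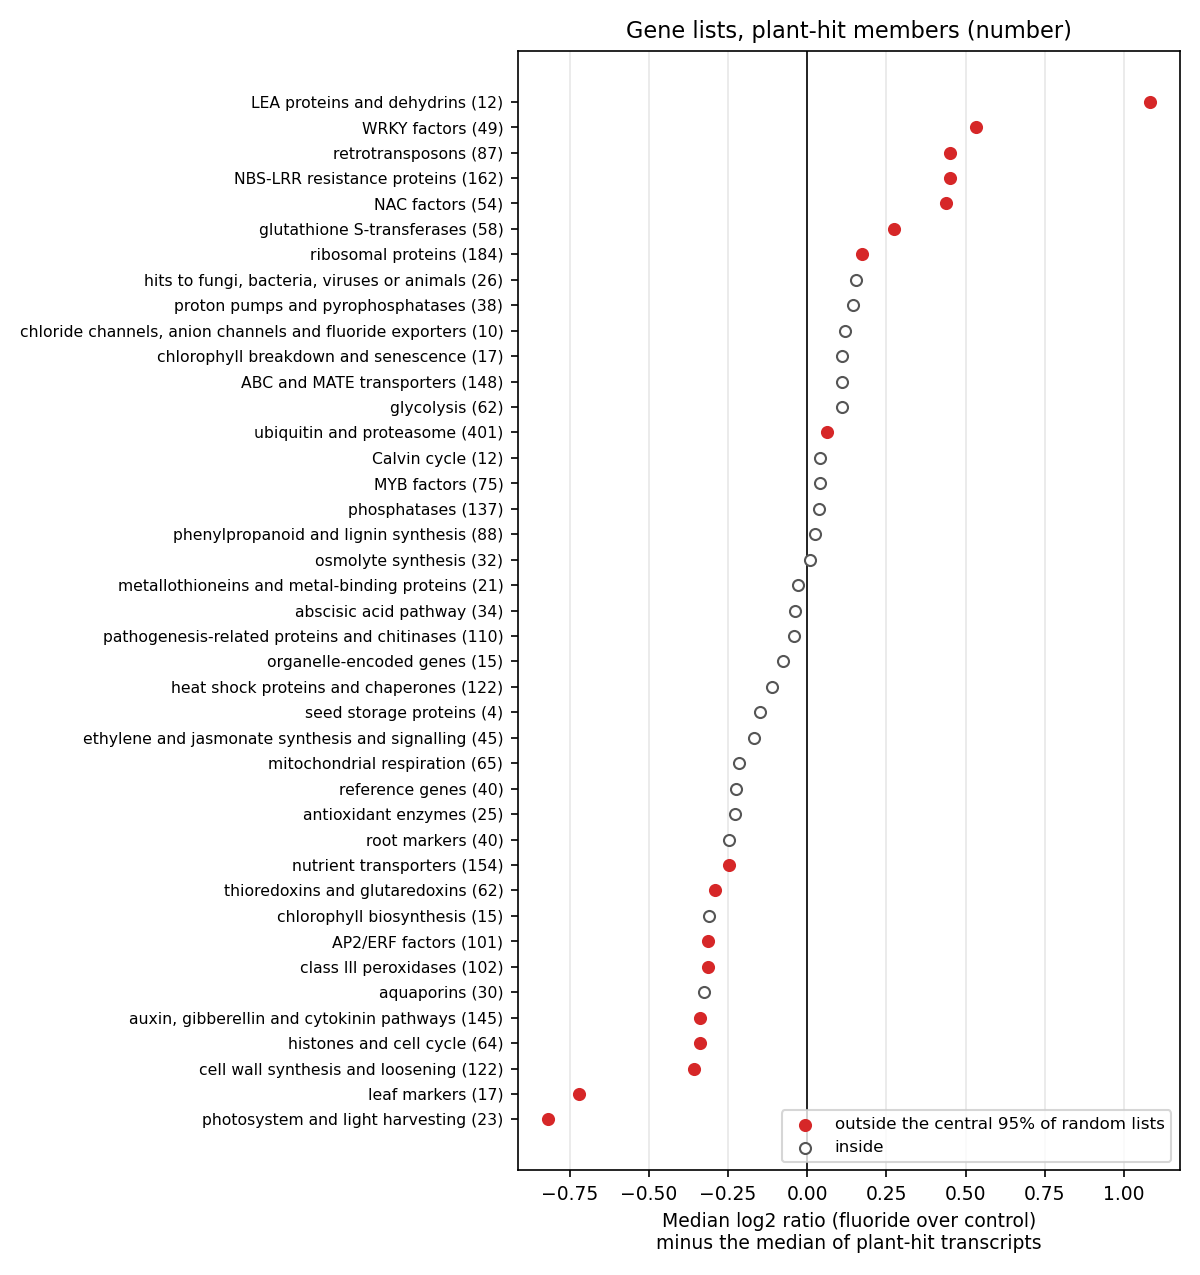
Median log2 ratio of each gene list's plant-hit members minus the median of all plant-hit transcripts (x axis), with the number of members after each list name (y axis); filled points lie outside the central 95% of 10000 random lists matched on expression. 17 of 41 lists lie outside, 8 above and 9 below, from photosystem and light harvesting (-0.82) to LEA proteins and dehydrins (1.08).

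WRKY factors, NAC factors and NBS-LRR resistance proteins lay above the plant-hit median, while AP2/ERF factors, many of them also stress regulators, lay below it. Of 49 plant-hit WRKY factors, 15 were at least 2-fold higher and 4 lower, and the list median lay 0.53 above (percentile 99.98). The 2 most abundant WRKY transcripts did not follow it as deposited: Os05g0343400, similar to WRKY transcription factor 33, was 1.72-fold lower (1.64 to 1.79), while WRKY transcription factor 25 was 1.10-fold lower (1.04 to 1.17) but higher once both libraries were scaled to the same total. Of 54 NAC factors, 13 were at least 2-fold higher and 5 lower (0.44 above, percentile 99.98), with NAC domain-containing protein 48 2.05-fold higher (1.98 to 2.13). Of 162 NBS-LRR resistance proteins, 38 were at least 2-fold higher and 12 lower, and 69.1% were higher at all (61.4 to 76.1%). Disease resistance protein RGA5 was 3.49-fold higher (2.36 to 5.31) and NBS-LRR-like protein A 3.15-fold lower (2.02 to 5.01). The 2 most abundant members were lower, disease resistance protein Pik-2 1.37-fold (1.28 to 1.46) and a protein similar to At4g33300 1.51-fold (1.43 to 1.60). AP2/ERF factors had 24 of 101 lower and 14 higher (percentile 0.12). Glutathione S-transferases, which conjugate toxic compounds, had 13 of 58 at least 2-fold higher and 6 lower (percentile 99.45). Their 2 most abundant members diverged, DHAR1 being 1.39-fold lower (1.35 to 1.44) and a GSTU6 transcript 1.63-fold higher (1.57 to 1.70). LEA proteins and dehydrins, which protect cells in drying tissue, had 6 of 12 higher and 2 lower. Dehydrin DHN1, the most abundant, was 2.35-fold lower (2.28 to 2.42), and late embryogenesis abundant protein 14 was 3.07-fold higher (2.21 to 4.35). The retrotransposon list, which also took in DNA transposons (24 of 87 higher, 14 lower), also lay above. Ribosomal proteins lay 0.17 above (percentile 100), with 11 of 184 higher and 3 lower, and the ubiquitin and proteasome list lay 0.06 above, with 38 of 401 higher and 25 lower.

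Pathogenesis-related proteins and chitinases went both ways. Of 110 plant-hit members, 28 were at least 2-fold higher and 14 lower, and the median stood at percentile 42.0. Chitinase 1, an enzyme that cuts fungal cell walls, was 36.1-fold higher (26.4 to 50.7), and the Bowman-Birk type bran trypsin inhibitor was 9.67-fold higher (9.14 to 10.2). The phenylpropanoid and lignin list had 19 of 88 higher and 10 lower (percentile 59.9). The ethylene and jasmonate list had 11 of 45 higher and 7 lower (percentile 22.4), with allene oxide synthase 3, which acts in jasmonate synthesis, 99.6-fold higher (69.2 to 149) and ETHYLENE INSENSITIVE 3-like 1 1.59-fold lower (1.56 to 1.63). In the abscisic acid pathway, with 4 of 34 higher and 5 lower (percentile 45.6), the epoxycarotenoid dioxygenases that open abscisic acid synthesis diverged. NCED4 was 15.9-fold higher (11.5 to 22.8), whereas NCED1 was 2.87-fold lower (2.75 to 3.0) and NCED3 3.91-fold lower (2.69 to 5.82).

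Cell wall, hormone pathway and cell cycle lists lay below the plant-hit median. Cell wall synthesis and loosening had 29 of 122 at least 2-fold lower and 9 higher (0.36 below, beneath all random lists), with expansin-B3, a wall-loosening protein, 2.47-fold lower (2.40 to 2.55) and a polygalacturonase 21.6-fold lower (15.8 to 30.2). Auxin, gibberellin and cytokinin pathways had 24 of 145 lower and 10 higher (0.34 below). Cytokinin dehydrogenase 1, which degrades cytokinin, went the other way, 18.6-fold higher (10.5 to 36.5). Histones and cell cycle genes had 9 of 64 lower and 2 higher (0.34 below), with cyclin-D3-2 3.29-fold lower (2.20 to 5.03). Their 2 most abundant members diverged, histone H3.3 being 1.13-fold higher (1.10 to 1.16) and histone H2A.4 1.35-fold lower (1.29 to 1.41). Outside these processes, class III peroxidases had 23 of 102 lower and 11 higher, nutrient transporters had 33 of 154 lower and 27 higher, and both medians also lay below. Thioredoxins and glutaredoxins had 5 of 62 lower and 5 higher, and their median was at percentile 2.34.

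Transcripts of a putative fluoride exporter, chloride and anion channels, and enolase went both ways. A CrcB-like transcript, described as a putative fluoride ion transporter (TRINITY_DN5876_c0_g1_i1), had 365 control and 349 fluoride reads, 1.27-fold lower (1.10 to 1.48). Scaling both libraries to the same total moves its log2 ratio of -0.35 up by 0.28. Most of the difference thus comes from the scaling, and the interval then spans a ratio of 1. 2 of the 3 transcripts described as chloride channel CLC-c had ratios of 1.04 (0.937 to 1.14) and 1.06 (0.907 to 1.23) as deposited. Their lower log2 bounds were -0.09 and -0.14, so the shift of 0.28 places both intervals above 1. The third CLC-c transcript, with 118 and 301 reads, was 2.10-fold higher (1.69 to 2.62). The more abundant CLC-g transcript had a ratio of 1.31 (1.11 to 1.55), and the anion channel SLAH1 was 1.78-fold lower (1.46 to 2.18). Rice enolase, a glycolytic enzyme that fluoride inhibits, had its 2 most abundant transcripts at 1.30-fold lower (1.17 to 1.43) and 1.11-fold lower (0.994 to 1.24), the latter higher once both libraries were scaled to the same total. 4 less abundant rice enolase transcripts had ratios of 1.15 to 1.59. As deposited, only chloroplastic enolase 1, at 1.59 (1.01 to 2.56), had an interval above 1. At the same total the intervals of cytosolic enolase 3 and enolase 1 (lower log2 bounds -0.04 and -0.07 as deposited) also lie above 1. The interval of the most abundant enolase (upper log2 bound -0.23 as deposited) then spans 1. An enolase transcript with a fungal hit had 0 and 357 reads. Of the plant-hit channel list, 1 of 10 was at least 2-fold higher and 0 lower. The reference genes with the highest means were lower except for 1 of 4: alpha tubulin was 1.58-fold lower (1.55 to 1.61), actin-7 1.68-fold lower (1.65 to 1.72), polyubiquitin 1.66-fold lower (1.63 to 1.70) and tubulin alpha-2 1.10-fold higher (1.06 to 1.14).

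Fungal hits raised the number of higher members in several lists. Mitochondrial respiration had 89 of 160 members at least 2-fold higher over all transcripts, 81 members being fungal hits, and a median log2 ratio of 4.54, or 2.83 with transcripts at 0 set to their bound. Its 65 plant-hit members had 2 higher and 0 lower. Antioxidant enzymes had 15 of 41 higher with all hits but 1 of 25 among plant hits. There the catalases, which break down hydrogen peroxide, diverged. Catalase-1 was 2.84-fold lower (2.77 to 2.90), and catalase isozyme A, with 25 control and 99 fluoride reads, was 3.25-fold higher (2.08 to 5.27). Ribosomal proteins went from 276 of 560 at least 2-fold higher with all hits to 11 of 184 among plant hits, glycolysis from 33 of 94 to 6 of 62, and proton pumps and pyrophosphatases from 32 of 72 to 3 of 38. The plant-hit medians of these 3 lists still stood on the high side of random lists, at percentiles 100, 96.1 and 97.3.

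The remaining lists fixed in advance stood inside the central 95% of random lists among plant hits. These were aquaporins (percentile 4.94), heat shock proteins and chaperones (16.6), reference genes (17.6), seed storage proteins (34.2), metallothioneins and metal-binding proteins (43.9), osmolyte synthesis (50.8), the list meant for organelle-encoded genes (52.5), MYB factors (65.0), chlorophyll breakdown and senescence (68.6), the list meant for hits to fungi, bacteria, viruses or animals (71.7), phosphatases (77), and ABC and MATE transporters (84.7). By their descriptions, the plant-hit members of the organelle list are nuclear-encoded proteins of photosystem II and of rRNA processing, so it does not measure organelle-encoded genes, and those of the list for hits to other organisms are mainly retrotransposon proteins. Within the other lists metallothionein-like protein 1B was 5.29-fold higher (5.04 to 5.56) and arginine decarboxylase, a polyamine enzyme, 2.88-fold lower (2.82 to 2.94).

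The authors' deposited table listed 1303 higher and 93 lower transcripts. In the authors' deposited table these lists held exactly the transcripts with an absolute log2 fold change of at least 2 and an unadjusted p under 0.05, while the smallest adjusted p of the 38900 transcripts was 0.715. Of the 1303 higher transcripts in the authors' deposited table, 1133 (87.0%) were fungal hits and 128 (9.82%) plant hits. Of the 93 lower ones, 82 were plant hits and 6 fungal hits. The first term of the authors' deposited table of gene ontology terms was translation, with 139 of 537 tested transcripts and an adjusted p of 9.7e-39. Of those 139 transcripts, 137 were fungal hits and 0 plant hits. In the authors' deposited table it was followed by cellular biosynthetic process (234 transcripts, adjusted p of 1.01e-17), cellular protein metabolic process (180, 1.01e-17), biosynthetic process (243, 1.06e-17) and protein metabolic process (182, 5.72e-16). Fungal hits supplied 230, 176, 239 and 178 of these transcripts.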

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

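All tests in this part were chosen after the results were seen. Reads of organisms other than rice, which the design does not name, were above their level in the control library for these groups, as a percent of fluoride reads: relatives of Bipolaris 2.89%, Candida and related yeasts 0.257%, smut fungi 0.248%, bacteria 0.122%, Fusarium and relatives 0.0984%, other Dothideomycetes 0.0593% and other fungi 0.0583%.

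The first pattern is the fungal reads of the fluoride library. A contamination that reached both libraries alike is argued against by the ratio of fungal shares, 50.8, while Drosophila hits had a ratio of 0.955. Other hits outside plants and fungi varied, with ratios of 0.951 for Homo, 5.26 for Mus, 13.2 for Cutibacterium and 0.0843 for Azospirillum. Unequal shares were thus not particular to fungi. Plant transcripts given a fungal hit by chance are argued against as well, since 98.0% of the fungal-hit transcripts were at least 2-fold higher, against 2352 of 18815 plant-hit transcripts. As the only source of the fungal reads in the control library, carry-over from the fluoride library is argued against, because the ratio of control to fluoride reads differed 283-fold among the 6 fungal groups. The high end came from the mixed groups: per 100 fluoride reads, other Dothideomycetes had 35.8 control reads and other fungi 20.7. Smut fungi had 0.126 and relatives of Bipolaris 1.23, so carry-over as a part of the source is not excluded. Whether the fungi grew because of the fluoride watering, were on those plants by chance or entered after harvest cannot be told apart with 1 library per group.

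The second pattern is that phytoalexin enzymes were higher and photosystem genes lower among plant hits. A larger share of root tissue in the fluoride library would raise root markers, which stood at percentile 3.0 of random lists, on the low side but inside the central 95%. The limit for this test was reworded to the central 95% after that value had been seen, so it is left open and not counted against. Whether the fungi or the fluoride go with these differences cannot be told apart, because the 1 library per group that had fluoride also had the fungi.

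The third pattern is 56 plant-hit transcripts with at least 100 reads in 1 library and at most 2 in the other, 30 of them present in the control and 26 in the fluoride library. An assembly that split 1 gene into isoforms by library would give opposite partners in the same assembly component. Only 23 of the 56 have another transcript of their component with a mean of at least 10, and 3 of these 23 (13%, upper bound 33.6%) have an opposite one, which leaves this open. Plants of different genotype in the 2 pots also stay open for these 56, since no genome data were used here.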

How the results depend on the processing

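The exact test on recovered reads, the restrictions to plant hits and their rescaling were chosen after seeing the data. The counts of 6521 higher and 2354 lower transcripts kept within 1.5 times under both pseudocounts, centring on the median and sums over the same best hit. They became 17983 and 5801 with no filter and 1686 and 1003 with a mean of at least 50, since other numbers of transcripts were counted. A fold of at least 4 gave 584 lower transcripts, and scaling both libraries to the same total gave 1538 lower. The exact binomial test on reads (adjusted p under 0.05, comparing libraries and not conditions; 100% of values were whole) called 11254 higher and 3865 lower. With plant hits alone the higher count was 2352, 2509 when centred on their own median, and 3342 when scaled to the same total, where the lower count was 1341. Fungal hits, left out there, were 3743 of the 6521. edgeR was not run. No named transcript at least 2-fold different changed direction under any alternative, but of all 254 the direction turned for 15 at the same total (WRKY transcription factor 25 and 1 enolase among them), 5 when centred on the median (CLC-c among them), 2 when summed over the same best hit and 1 when centred on the plant hits.

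Of the 41 lists, 17 had a median outside the central 95% of random lists with all hits, and 15 to 18 under the alternatives. The share of higher members crossed 50% for 0 to 10 of the 41 lists, depending on the alternative (8 with plant hits alone). Among the 17 lists this happened to 5. With plant hits alone it was 41.7% for the Calvin cycle, 28% for antioxidant enzymes (36.0% centred, 48.0% at the same total) and 21.5% for mitochondrial respiration (27.7% centred). With a mean of at least 50 normalized counts it was 46.2% for antioxidant enzymes, 47.2% in the share higher: mitochondrial respiration, and 41.4% in the share higher: hits to fungi, bacteria, viruses or animals. The share higher: nutrient transporters reached 52.3% with no filter on low values and 56.5% with both libraries scaled to the same total. For the settings other than plant hits alone, the cause was not tested. The authors deposited calls for 1396 transcripts, of which 0 had an adjusted p under 0.01 and 210 were plant hits. No paired analysis was possible because each group has 1 library. Depth limits the transcripts with 0 to 3 reads, whose ratios have wide intervals or only a bound.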

Other observations

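Tests and lists in this part were chosen after the data were examined. Among fungal hits, Woronin body proteins, which plug damaged hyphae, had 8 control and 1883 fluoride reads, chitin synthases 24 and 1209, alcohol oxidases 6 and 3546, and melanin synthesis enzymes 10 and 1319. Enzymes that degrade plant cell walls had 76 and 5657 reads over 127 transcripts, and fungal ribosomal proteins 922 and 41084 reads over 475 transcripts. The most abundant well-described fungal transcript, ATP synthase subunit a of Stemphylium, had 22 and 5941 reads. Hits to amoebae differed among genera, with 22 and 1522 reads for Planoprotostelium and 18 and 1132 for Naegleria, but 349 and 167 for Acanthamoeba.

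In rice, terpenoid phytoalexin enzymes had 16 of 31 plant-hit members at least 2-fold higher and 2 lower, with a median log2 ratio 1.91 above the plant-hit median, beyond all 10000 random lists. The list was written after some of these genes had been seen, so it is not independent evidence. Its 2 most abundant members went the other way: ent-isokaurene C2/C3-hydroxylase was 1.37-fold lower (1.25 to 1.49), and beta-sesquiphellandrene synthase had 1325 control and 537 fluoride reads (2.71 to 3.32-fold lower). Xylanase inhibitors, chitinases and thaumatins had 26 of 56 higher and 4 lower (0.66 above), and cysteine-rich receptor kinases 18 of 44 higher and 4 lower (0.76 above). The serotonin and tryptamine list had 6 of 16 higher and 3 lower, and tryptophan synthase alpha chain was 2.64-fold higher (2.41 to 2.90). Laccases (5 of 20 higher, 1 lower) and iron deficiency genes (5 of 28 higher, 3 lower) stood inside the central 95% of random lists, although IRON-RELATED TRANSCRIPTION FACTOR 2 was 67.3-fold higher (30.7 to 184).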
